A study of Homo sapiens with 8 samples.

How the data were processed

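The 8 libraries were assigned to groups from their titles (CLIP-seq and uninfected H9 cells) or their treatment labels (knockdown and small RNA libraries). For small RNA the series description names H9 knockdown cultures instead, and the labels were followed. The groups held 1 library each, so no comparison had replicates and no test between conditions was possible. Per the labels' protocols, CLIP-seq used an antibody against endogenous LIN28 in H9 cells and one against the V5 tag in LIN28-V5 293 cells. Messenger RNA was selected for poly(A), fragmented and sequenced with strand information from a band of 110 to 160 bp. Small RNA libraries were made from 2 µg of total RNA with 13 cycles of PCR. The H9 small RNA library used the supplied adapters and a band of 85 to 115 bp, while both 293 libraries used other adapters and a band of 135 to 160 bp.

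Per the submitters' processing notes, Bowtie 0.12.2 and the hg18 build were used for the CLIP and mRNA data, and Bowtie and the hg19 build for the small RNA data. The cluster caller, the counting rules and the filters are not given in the sources used here. The CLIP files hold clusters as BED intervals with a strand, a gene number, a whole-number score and an inner region. The cluster score is the authors' own, its meaning is not stated in the file, and it was used only to rank clusters within a list. A gene number always stood on 1 chromosome and 1 strand and was taken as the authors' number of a gene. The authors deposited mRNA levels as RPKM per UCSC known gene identifier, per the file headers. The knockdown and control knockdown tables list the same 12894 genes, none at 0, and in each gene the larger of both values is at least 0.500 RPKM. The uninfected table lists 13433 genes, and 12533 genes are in all 3. The authors deposited miRNA levels as RPM, per the file headers, rounded to whole numbers, and for this reason they were handled as scores without a fixed range rather than as counts.

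The miRNA tables hold 198 entries under 136 names. Of these names 62 are listed 2 times, with no word on what sets the entries apart, and the entry with the larger sum over the libraries is called the higher entry here. Loci of the same miRNA with equal values in all 3 libraries (let-7a, let-7f, miR-26a and miR-101) were counted once, which left out 4 entries and kept 194. Family lists used the higher entry of each name. Sums were taken over all 198 entries, with the equal loci counted each time. They were 223082 RPM in Flp-In-293, 236380 RPM in LIN28-V5 293 and 875597 RPM in H9, and shares of the listed RPM refer to them. The reads that RPM refers to are not stated, so these sums do not give the depth of a library.

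Depth was sought in the low values. In RPKM, genes below 0.7 RPKM in the control knockdown library had ratios to the other libraries near whole multiples of a fixed step: 229 of 365 genes (62.7%) for LIN28 knockdown at a step of 0.226, and 89 of 226 (39.4%) for uninfected cells at 0.138, within 1.5% and up to the multiple 8. Ratios blurred at random gave 9.46% and 11.0%. These steps give relative depths of 4.43 and 7.23, and the absolute depth is unknown. For the small RNA data, rounding hid the steps: the best step under 30 RPM was 1.77 RPM in LIN28-V5 293, which took in 94.6% of 74 values while allowing 55.2% of the whole numbers, and no step was as selective in the other libraries. Whole reads were not recovered, the depth of these libraries is unknown, and no interval is given for miRNA values.

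Fold changes were computed as log2 of the ratio after adding 1 RPKM or 1 RPM to both values, which understates the change of low values. The spread of mRNA ratios by expression level and the variance set apart by a library used log2 values without this addition. mRNA counts took genes with at least 1 RPKM in either library of a contrast and a limit of 2-fold, and miRNA counts took entries with at least 10 RPM in either library. To say whether a miRNA family stood apart, the median of its log2 fold changes was placed among 10000 random lists of other entries of the same size. The lists were matched in 5 classes of mean level and drawn with replacement, with 95% of their medians between percentiles 2.5 and 97.5. Matching in 20 classes had been written down for gene lists, and 5 were used because the entries are few; the placing of miRNA families among random lists was itself added after the files were seen. Clusters overlapped when they shared at least 1 nt on the same strand, and the background was the mean overlap after shifting each cluster by 1000 nt upstream and downstream. Shares of clusters have 95% exact (Clopper-Pearson) binomial intervals. Distances between inner regions were compared with 100 random points drawn within each pair of clusters. The number of genes shared by chance was the product of both gene counts divided by the 11920 genes with at least 1 RPKM in uninfected H9 cells. Gene numbers and mRNA identifiers cannot be linked, so genes with clusters could not be limited to these genes. A background over all gene numbers up to the highest, 26568, was chosen after seeing the data.

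Named items followed a rule: every listed let-7, miR-302, miR-367 and miR-371 to miR-373 member, the 5 highest and the 5 lowest entries by log2 fold change among those with at least 100 RPM, the 10 clusters with the highest score and the 10 genes with most clusters in each line, from which the text takes those that stand out, and the mRNA genes whose smaller change against both other libraries was largest among those with at least 5 RPKM in either infected library. Only 1 of 13794 mRNA identifiers matched the gene name tables of the GRCh38.p14 assembly, so at most 2 identifiers are printed in each direction. The planned level of LIN28A, the planned gene lists and the fold change of CLIP target genes need gene names and were not analysed here, nor were sequence motifs or the position of clusters within genes, which need the hg18 sequence and annotation. Groups, fold rules, lists, the naming rule and most other settings were chosen before the data were examined, and 8 settings were chosen after seeing the data.

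The other settings were other pseudocounts, minimum levels and fold limits, scaling by the median or by a trimmed mean of log ratios (TMM), other overlap rules and shifts, subsets of clusters by score, and another baseline library. Some of the steps were tested on simulated data. For LIN28 knockdown against control knockdown, 12533 genes were simulated, with 100 of them raised 4-fold and 100 lowered 4-fold. The 2-fold limit found 100% of the raised and 88% of the lowered genes. Detection of changed genes near the minimum of 1 RPKM was not tested. These shares thus do not describe such genes, nor 2-fold counts that include them. In the same contrast, a list of 30 raised genes stood at percentile 100. Of 100 unchanged lists 9% lay outside percentiles 2.5 to 97.5, more than these limits set. Gene lists were not analysed here, so this list test covers no result given, and the placing of miRNA families was not simulated. The relative depth step recovered a ratio of 0.225 that was set to 0.225. The overlap step found 20.1% of 20147 clusters where 20.1% had been copied. A copy overlaps its source by construction, so this checks only the counting of overlaps and does not test partial overlaps. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.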

Results

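LIN28 is an RNA-binding protein of embryonic stem (ES) cells that binds precursors of the let-7 microRNAs (miRNAs) and blocks their maturation, and it also binds messenger RNAs. The data comprised 8 libraries, 1 for each group. LIN28-bound RNA was sequenced after cross-linking and immunoprecipitation (CLIP-seq) from H9, a human ES cell line, and from LIN28-V5 293, a stable line made from Flp-In-293 cells (HEK293 with a recombination site) that carries LIN28 fused to the V5 epitope tag. Messenger RNA was sequenced from 3 H9 cultures: uninfected cells, cells infected with a lentivirus carrying an shRNA against LIN28A (LIN28 knockdown), and cells infected with a lentivirus carrying an shRNA against GFP (control knockdown), both harvested 72 hours after infection. Small RNA was sequenced from Flp-In-293, LIN28-V5 293 and H9 cells per the library labels, which were followed here although the series description names H9 knockdown cultures for this assay. With 1 library per group there was no replicate error, so the differences below describe single libraries and carry no p-value between conditions.

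The first comparison asked whether LIN28 bound the same transcripts at the same positions in ES cells and in 293 cells. The H9 library gave 20147 clusters in 5418 genes and the LIN28-V5 293 library 11535 clusters in 5482 genes. LIN28-V5 293 clusters overlapped 3996 H9 clusters on the same strand (19.8%, 95% exact binomial interval 19.3 to 20.4%), against 1.06% once the H9 clusters were shifted by 1000 nt and 2.03% with a shift of 300 nt. In the other direction, 4037 LIN28-V5 293 clusters overlapped an H9 cluster (35.0%, interval 34.1 to 35.9%), against 1.84% after the shift. The shift ran along the genome, so a shifted cluster can leave the exon, or the transcript, in which it lay. Since exons were not located here, the excess over the shift does not separate a shared site from a shared exon. Clusters occurred in both lines in 3505 genes, which made up 64.7% of the H9 genes and 63.9% of the LIN28-V5 293 genes, and 2313 of these genes (66.0%) held an overlapping pair of clusters. A further 1913 genes held clusters in H9 alone and 1977 in LIN28-V5 293 alone.

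The cluster with the highest score in H9 lay on the plus strand of chromosome 12 from 20595633 to 20595760 (hg18, as are all coordinates here), in the gene numbered 5344 by the authors. The LIN28-V5 293 cluster with the second highest score lay at the same place, from 20595633 to 20595763, with a score of 2605 beside 7792 in H9. The highest score in LIN28-V5 293, 2752, belonged to the cluster from 217072927 to 217072987 on the plus strand of chromosome 2, which an H9 cluster with a score of 410 overlapped. All 10 of the highest-scoring LIN28-V5 293 clusters overlapped an H9 cluster, and 6 of the 10 highest-scoring H9 clusters overlapped a LIN28-V5 293 cluster. Of the other 4 H9 clusters, a pair lay in gene number 5198 on the minus strand of chromosome 12 (7963740 to 7963915, score 2410, and 7964501 to 7964700, score 1835). The remaining pair lay on the minus strand of chromosome 9, from 14709090 to 14709289 (score 3820) and from 98834877 to 98835046 (score 1526). Gene number 15046, whose clusters spanned 215933840 to 216007780 on the minus strand of chromosome 2, held 39 H9 and 8 LIN28-V5 293 clusters, among them 3 of the 10 highest-scoring H9 clusters. The gene with most H9 clusters was number 642 on the plus strand of chromosome 1 (39469449 to 39724738), with 57 clusters in H9 and 7 in LIN28-V5 293. Gene number 7526 on the plus strand of chromosome 14 (101515559 to 101586870) ranked among the top 10 in both lines, with 34 and 19 clusters. The files number these genes without naming them, and whether a cluster lay in an exon, an intron or an untranslated region was not analysed here.

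Overlap was higher for clusters with higher scores in both lists. Over 4 equal classes of score it went from 11.3% in the lowest class of H9 clusters to 33.4% in the highest, and from 22.2% to 52.4% for LIN28-V5 293. At the top of the H9 list the share was 43.3% for the 1000 highest-scoring clusters (interval 40.2 to 46.4%), above that of the highest class. It was 37.0% for the 100 highest-scoring clusters, with an interval of 27.6 to 47.2% that leaves open whether the share rose or fell further. For LIN28-V5 293 the shares were 63.2% for the 1000 and 85.0% for the 100 highest-scoring clusters. The shifted background was not computed by class, and classes were not matched on cluster length. The authors marked a short inner region in each cluster, 9 nt long in 72.0% of H9 and 48.7% of LIN28-V5 293 clusters. In the 3996 overlapping pairs the centres of these inner regions lay a median of 5 nt apart, and 52.8% lay within 5 nt of each other, against 27.1% for points drawn at random inside the same clusters. In the 1857 pairs with inner regions of 9 nt on both sides the median was 8 nt, and 40.3% lay within 5 nt, against 17.3% at random. The centre of an inner region of 9 nt cannot reach the ends of its cluster, while a random point can. Some of both differences can thus arise by construction, and how much was not tested. Scores of paired clusters were weakly related, with a Spearman's rho of 0.25 across pairs, which are not independent replicates. H9 genes held more clusters each (mean 3.72 against 2.10) and H9 clusters were longer (median 32 against 18 nt), while the lowest listed score was 12 in H9 and 9 in LIN28-V5 293.

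Whether the 3505 genes with clusters in both lines exceed the number that independent lists would share depended on the genes counted as able to carry clusters. Independent lists would share 2492 genes over the 11920 genes with at least 1 RPKM in uninfected H9 cells, a ratio of 1.41. With the 7549 genes with at least 5 RPKM the number was 3934, more than the shared genes seen (ratio 0.891). Neither list could be limited to the genes of a background, so a smaller background raises this number by construction. For these reasons neither an excess nor a lack of shared genes is claimed here. The overlap of positions does not rest on this background. Requiring 50% of each cluster to be shared lowered the overlap of H9 clusters to 8.73%, with 0.166% after the shift. The intervals cover counting error of the clusters in these libraries only, and the lines were precipitated with different antibodies, against LIN28 in H9 and against V5 in LIN28-V5 293.

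**Figure D1:**
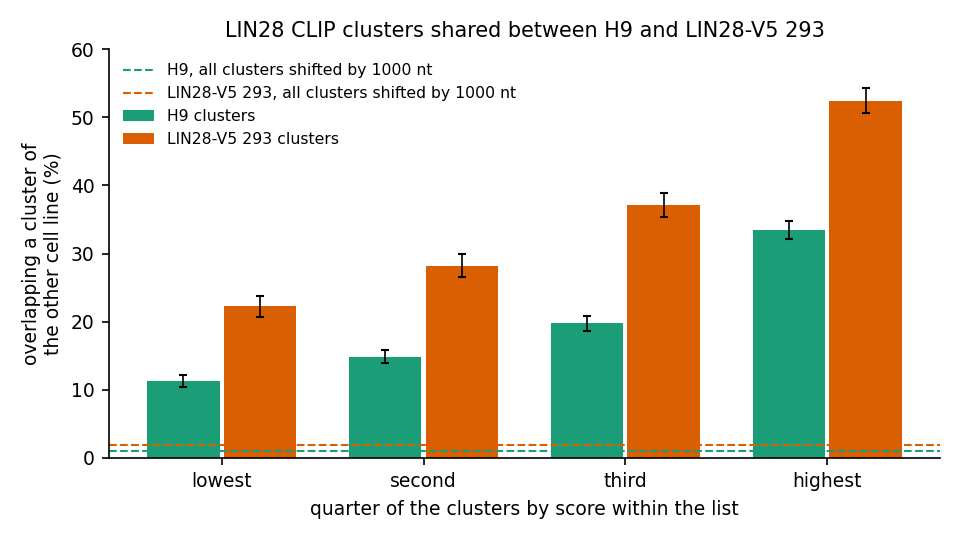
Share of LIN28 CLIP clusters of each cell line that overlap a cluster of the other line on the same strand (percent, y axis), by 4 equal classes of the clusters ranked by score within their own list (x axis). Bars are shares of 1 library each, error bars are 95% exact binomial intervals, and dashed lines show all clusters after a shift of 1000 nt; the shares reach 33.4% for H9 and 52.4% for LIN28-V5 293 in the highest class, against 1.06% and 1.84% after the shift.

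The second comparison asked which miRNAs differed between 293 cells with and without LIN28-V5. All 9 listed members of the let-7 family, miRNAs that promote differentiation, were lower in the LIN28-V5 293 library, 6 of them at least 2-fold on the log2(RPM + 1) scale. Let-7f read 3009 RPM (the authors' normalized unit) in Flp-In-293 and 808 RPM in LIN28-V5 293 (log2 fold change -1.90), let-7g 369 and 103 RPM (-1.83), and let-7i 68 and 18 RPM (-1.86). MiR-98, a let-7 family member by sequence, read 198 and 65 RPM (-1.59). The member with the highest level, let-7a, differed least, with 17172 RPM in Flp-In-293 and 15917 RPM in LIN28-V5 293 (-0.11).

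Let-7c read 501 RPM in Flp-In-293 and 215 RPM in LIN28-V5 293 (log2 fold change -1.22), let-7b 295 and 148 RPM (-0.99), let-7e 458 and 345 RPM (-0.41), and let-7d, near the lower end of the list, 12 and 4 RPM (-1.38). The median log2 fold change of the family was -1.38, below the medians of all 10000 random lists of 9 other miRNAs matched on level, 95% of which lay between -0.12 and 0.71. Summed over its members, the family read 22082 RPM in Flp-In-293 and 17623 RPM in LIN28-V5 293, and without let-7a 4910 and 1706 RPM. The 85 other miRNA entries with at least 10 RPM in either library had a median of 0.43 and an SD over entries of 0.82, and 23 of them (27.1%) were lower in LIN28-V5 293. Among these entries 14 were at least 2-fold higher and 4 at least 2-fold lower, and none was as low as the let-7 median (lowest -1.22). The place of the family below all random lists follows from this and is not separate support.

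Outside the family, the highest log2 fold changes among the 39 entries with at least 100 RPM belonged to miR-769 (956 RPM in Flp-In-293 and 2972 RPM in LIN28-V5 293), 1 of the 2 entries of miR-1307 (55 and 172 RPM), miR-186 (355 and 681 RPM), the higher entry of miR-30e (431 and 811 RPM) and miR-374a (250 and 441 RPM). The lowest log2 fold changes were small by comparison: -0.60 for the lower entry of miR-30e (192 and 126 RPM), -0.44 for miR-221, -0.34 for miR-20a, -0.33 for miR-375 and -0.31 for miR-34a. MiR-10a, encoded among the HOXB genes, supplied most of the listed RPM in both lines. It read 121222 RPM in Flp-In-293 and 131067 RPM in LIN28-V5 293, which were 54.3% and 55.4% of all 198 entries, equal loci included. In the list of miR-17-92 and its paralogs, a group that promotes proliferation, 5 of 11 members read higher and 6 lower, with a median of -0.03 that lay at percentile 16.4 of its random lists. This balance rested on the scaling: with the median of all entries set to 0, 2 members read higher and 9 lower (median -0.38), with miR-106b, miR-17 and miR-92a turning lower. With the median of the other miRNAs set to 0, all 9 let-7 members stayed lower (median -1.72, highest -0.54), and the split of the other entries at the 2-fold limit moved from 14 higher and 4 lower to 11 higher and 9 lower. Of the 18 other entries past the 2-fold limit, 2 had at least 100 RPM in either library.

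**Figure D2:**
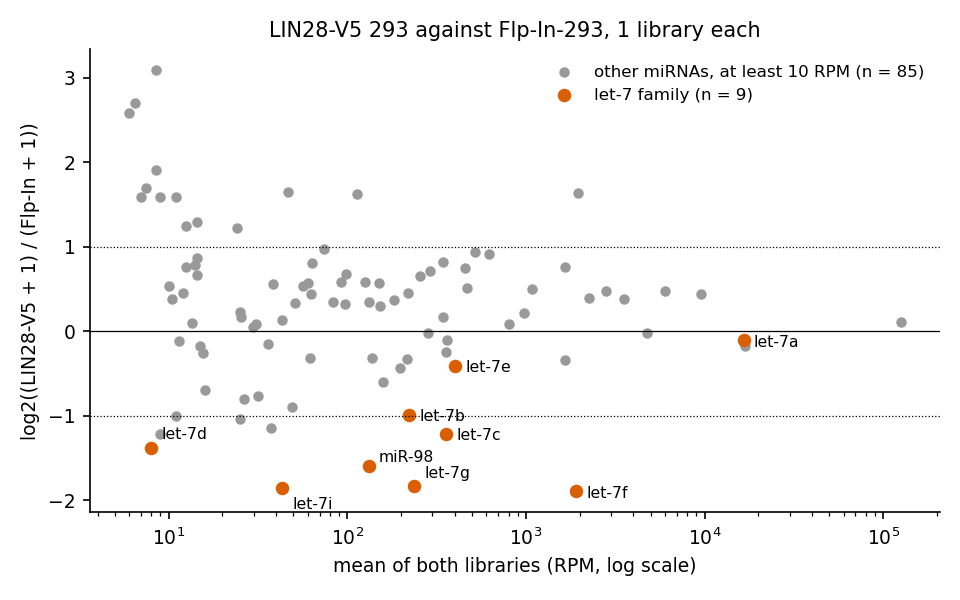
Log2 fold change of LIN28-V5 293 over Flp-In-293, with 1 RPM added to each value (y axis), against the mean of both libraries in RPM (x axis, log scale). Each point is 1 miRNA entry of 1 library per line, and dotted lines mark 2-fold; the 9 let-7 family members lie between -1.90 and -0.11, and the 85 other entries have a median of 0.43.

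The third comparison set H9 ES cells beside Flp-In-293. The miR-302 and miR-367 group, which is characteristic of pluripotent cells, dominated the H9 library. MiR-302b alone read 509541 RPM, 58.2% of all 198 entries with equal loci included, against 3 RPM in Flp-In-293. MiR-302d read 24480 RPM against 7 RPM, miR-302a 21846 RPM against 1 RPM, miR-302c 40942 RPM and miR-367 12338 RPM, the last pair being listed at 0 in Flp-In-293. MiR-371, miR-372 and miR-373, also ES cell miRNAs, read 11, 151 and 455 RPM in H9 and were listed at 0 in Flp-In-293. The let-7 family read lower in H9 for 8 of 9 members, 7 of them at least 2-fold, with let-7a at 1976 RPM against 17172 RPM and let-7b at 13 RPM against 295 RPM. Let-7d was the exception at 30 RPM against 12 RPM, and it turned lower (-0.31) when the median of all entries was set to 0.

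Of the members of miR-17-92 and its paralogs, 10 of 11 were at least 2-fold higher in H9, among them miR-20b (40183 RPM against 40 RPM), miR-363 (26434 RPM against 34 RPM) and miR-20a (68443 RPM against 1856 RPM). MiR-25 was lower, with 1064 RPM against 8064 RPM, and miR-92a, at 91 RPM against 30 RPM, turned lower when the median of all entries was set to 0. The median log2 fold change of this list was 3.81, at percentile 63.2 of random lists matched on level. The let-7 median was -2.01, at percentile 0.38, but against LIN28-V5 293 in place of Flp-In-293 it was -0.74, at percentile 8.26, within the random lists and with 2 of 9 members higher in H9. MiR-10a was lower, with 242 RPM in H9 against 121222 RPM, as was miR-615, an intronic miRNA of the HOXC genes, listed at 0 in H9 against 387 RPM. MiR-192 read 131 RPM against 5038 RPM, the higher entry of miR-181b-1 10 RPM against 200 RPM, and miR-342 10 RPM against 184 RPM.

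Over all 115 entries with at least 10 RPM in either library, together with the let-7 members, 95 differed at least 2-fold, 64 higher and 31 lower in H9. Setting the median of all entries to 0, a shift of 1.66 on the log2 scale, moved this split to 43 higher and 49 lower. The H9 library was made with other adapters and a gel band of 85 to 115 bp, against 135 to 160 bp for both 293 libraries. All 198 listed entries, equal loci included, summed to 875597 RPM in H9 but to 223082 RPM in Flp-In-293. Cell line and library preparation thus cannot be told apart.

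**Figure D3:**
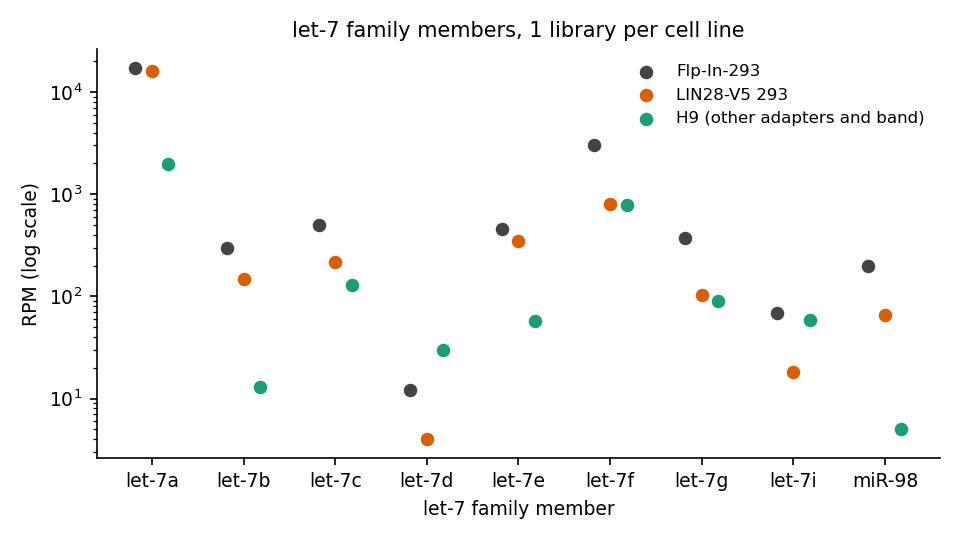
Level of each let-7 family member in RPM (y axis, log scale) by member (x axis) in Flp-In-293, LIN28-V5 293 and H9, 1 library each. Let-7a stands highest in all 3, at 17172, 15917 and 1976 RPM, and each member lies lower in LIN28-V5 293 than in Flp-In-293.

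The last comparison concerned messenger RNAs in H9 cells after LIN28 knockdown. The targeted gene itself and the lists of splicing factors, pluripotency genes and let-7 targets were not analysed here, because the tables name genes by UCSC known gene identifiers and the files do not pair these with symbols. The identifier that was lower in the LIN28 knockdown by the widest margin against both other libraries was uc001bmi.1, at 31.8 RPKM against 262 RPKM in the control knockdown and 224 RPKM in uninfected cells (the smaller log2 fold change, against uninfected cells, was -2.78). The next, uc010iuh.1, read 0.594 RPKM against 6.13 and 13.9 RPKM. The identifiers higher by the widest margin were uc009vvg.1 (11.4 RPKM against 1.11 and 0.161 RPKM) and uc003qar.1 (17.7 RPKM against 2.88 and 0.804 RPKM).

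Of 12028 genes with at least 1 RPKM in either library, 821 differed at least 2-fold between LIN28 knockdown and control knockdown on the log2(RPKM + 1) scale, 381 higher and 440 lower (28 higher and 55 lower with a pseudocount of 5 RPKM). The contrast without LIN28 knockdown, control knockdown against uninfected, gave more: 1031 of 12046 genes, 378 higher and 653 lower, a lean toward lower genes that was absent with a minimum of 20 RPKM (53 higher and 55 lower) or a pseudocount of 5 RPKM (73 higher and 60 lower). LIN28 knockdown against uninfected gave 780 of 11922 genes, 261 higher and 519 lower, and this lean was smaller under the same settings (45 higher and 62 lower, and 57 higher and 69 lower). Among 8035 genes with at least 5 RPKM in either infected library, 113 stood at least 2-fold apart from both other libraries in the LIN28 knockdown (39 higher and 74 lower). The control knockdown set 163 genes apart (78 higher and 85 lower) and the uninfected library 112 (34 higher and 78 lower). Genes that reached 5 RPKM in uninfected cells alone could not enter, which limits the uninfected count but not the others. The number for LIN28 knockdown was thus close to that of the uninfected library and below that of the control knockdown, the shallowest library. With 1 library per group these counts do not decide whether LIN28 knockdown changed genes.

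The spread over genes of the log2 ratio, taken here without an added RPKM, was smaller at higher expression. Its SD was 1.33 under 1 RPKM and 0.34 at 50 RPKM or more for LIN28 knockdown against control knockdown. At 50 RPKM or more it was 0.37 for control knockdown against uninfected and highest, 0.40, for LIN28 knockdown against uninfected, the contrast without the shallowest library. These SDs are thus on another scale than the 2-fold counts above. Ratios of low values showed the control knockdown library to be the shallowest: a read in it stood for as much RPKM as 4.43 reads in the LIN28 knockdown and 7.23 reads in the uninfected library. The 2-fold count of the first contrast ranged from 83 with a pseudocount of 5 RPKM to 1790 with one of 0.1 RPKM.

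**Figure D4:**
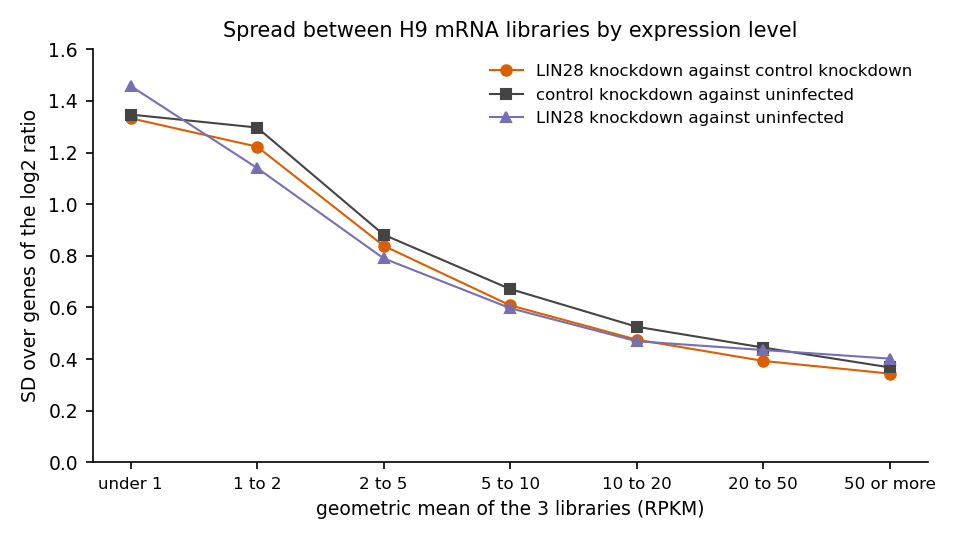
SD over genes of the log2 ratio, without an added RPKM, between pairs of H9 mRNA libraries (y axis). The x axis gives classes of expression by the geometric mean of the 3 libraries in RPKM. The contrast of LIN28 knockdown with control knockdown falls from 1.33 under 1 RPKM to 0.34 at 50 RPKM or more. The contrast of control knockdown with uninfected cells falls from 1.35 to 0.37, and that of LIN28 knockdown with uninfected cells from 1.46 to 0.40.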

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

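Of 46 alternative settings, 19 left a result the same within its limits, 26 moved it and 1 reversed it. Among these settings, a minimum of 20 RPKM, uninfected cells as baseline, equal numbers of clusters, all gene numbers as background and scaling without miR-10a were chosen after seeing the data. The 2-fold gene counts, in the order LIN28 knockdown against control knockdown (821), control knockdown against uninfected (1031) and LIN28 knockdown against uninfected (780), became 1790, 1962 and 1489 with a pseudocount of 0.1 RPKM, 83, 133 and 126 with 5 RPKM, 440, 627 and 496 with a minimum of 5 RPKM, 70, 108 and 107 with a minimum of 20 RPKM, and 3021, 3386 and 2696 with a limit of 1.5-fold. In each setting the count without LIN28 knockdown stayed above the first count, but its lean toward lower genes (378 higher and 653 lower) did not hold with a pseudocount of 5 RPKM (73 and 60) or a minimum of 20 RPKM (53 and 55), that of LIN28 knockdown against uninfected (261 and 519) was smaller there (57 and 69, 45 and 62), and the split of the first contrast (381 and 440) leaned lower with a pseudocount of 5 RPKM (28 and 55). By construction, fewer genes entered under the higher minimums. The overlap of H9 clusters (19.8%) became 8.73% with 50% of each cluster shared, 18.2% for the 50% of both lists with higher scores and 25.4% for as many H9 as LIN28-V5 293 clusters, with backgrounds from 0.166% to 1.38%, and a shift of 300 nt raised the background of the 19.8% from 1.06% to 2.03%. The 3505 genes with clusters in both lines, 1.41 times the chance number, became 1749 with at least 2 clusters required (2.16 times). With genes of at least 5 RPKM as background the 3505 genes fell below the 3934 by chance (0.891 times), and with all gene numbers they were 3.14 times the chance number. The let-7 median in LIN28-V5 293 against Flp-In-293 (-1.38) became -1.18 with a pseudocount of 10 RPM, -1.72 with the median of the other miRNAs at 0, -1.22 for members with at least 100 RPM and -1.42 without miR-10a, with every member lower each time. Other miRNA entries past 2-fold (18) became 5 with a pseudocount of 10 RPM, 2 with a minimum of 100 RPM and 45 with no minimum. Apart from the construction of each setting, the cause was not tested. Other settings for the LIN28A level, the gene lists and the CLIP targets were not run, since these results need gene names. No paired analysis was possible because each group had 1 library, and for the same reason no library was left out in turn. The shallow control knockdown library limits low mRNA values, and the depth of the small RNA libraries is unknown.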

Other observations

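The let-7 settings in this part were chosen before the data were examined and their limits as tests after the results were seen, equal numbers of clusters was a setting chosen after seeing the data with limits set before its own result, and the other tests were chosen after the results were seen. Let-7a took a larger share of the family in LIN28-V5 293 (90.3%) than in Flp-In-293 (77.8%) or H9 (63.0%). Several names listed 2 times had entries that went apart: of 18 names with both entries at 10 RPM or more in either 293 library, 12 had entries that differed in the same direction and 6 in opposite directions. The entries of miR-30e had log2 fold changes of 0.91 and -0.60 and those of miR-125a 0.50 and -1.22, while both entries of miR-769 were higher (1.64 and 1.65). Low values of ES cell miRNAs in LIN28-V5 293 and Flp-In-293 were 18 and 7 RPM for miR-302d, 14 and 3 RPM for miR-302b, 11 and 1 RPM for the lower entry of miR-302a, 4 and 0 RPM for the higher and 0 and 1 RPM for the lower entry of miR-302c, and 2 and 0 RPM for miR-373, with miR-367, miR-371 and miR-372 listed at 0 in both lines. Of the miR-302 and miR-367 members 4 of 5 read higher, 3 of them at least 2-fold, and 0 lower. Among random lists, miR-302 and miR-367 stood at percentile 63.3 and miR-371 to miR-373 at percentile 14. This placing decides nothing, since the random lists drew on entries with at least 10 RPM and most of these members read less. With miR-371 and miR-372 at 0 in both lines, the median of their list was 0 whatever miR-373 read. The values of ES cell miRNAs and of miR-125a were chosen after they were seen.

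The let-7 family was lower in LIN28-V5 293 than in Flp-In-293, with all 9 members lower. A difference in scaling of the whole library does not account for it, since the family's median stayed at -1.72 with the median of the other miRNAs set to 0, beside an SD of 0.49 over the other entries with at least 100 RPM. Counting error of low values does not account for it either, since the 7 members with at least 100 RPM had a median of -1.22 and were all lower. With 1 library per group, the effect of LIN28-V5, which is known to block let-7 maturation, cannot be told apart from any other difference between the 2 cultures or libraries.

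Between LIN28 knockdown and control knockdown 821 genes stood at least 2-fold apart, and the control knockdown library was the shallowest. The LIN28 knockdown library set apart 0.618 times as much variance of the log2 values as the control library over 8110 genes with a mean of 2 to 20 RPKM. If variance scaled with depth alone, this ratio would be 0.226. Over 1512 genes with a mean of 20 to 50 RPKM it was 0.897, and the uninfected library set apart 1.43 times as much as the control. A difference particular to either culture moves this ratio, up for LIN28 knockdown and down for the control, so with 1 library per group it decides nothing, and how much of the pattern is counting error stays open. Whether LIN28 knockdown itself sets genes apart stays open: it set 113 genes 2-fold apart from both other libraries, the control knockdown 163 and the uninfected library 112. The minimum level was asked of the infected libraries only, which limits the uninfected count.

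The share of CLIP clusters on a chromosome, H9 over LIN28-V5 293, was lowest on the gene-dense chromosomes 19 (0.517) and 17 (0.557) and highest on the gene-poor chromosome 4 (1.94). Across 23 chromosomes, in these 2 libraries made with different antibodies, the log2 ratio was related to gene numbers per megabase (Pearson's r -0.76, p 2e-05 by permuting chromosomes, which does not test the cell lines, Benjamini-Hochberg adjusted over 4 relations 2.67e-05; Spearman's rho -0.68, permutation p 0.00041), and r was -0.61 without the 2 chromosomes farthest from the median density. Genes with clusters, counted once each, followed density as well (r -0.79, permutation p 2e-05, adjusted 2.67e-05; -0.67 without the same 2 chromosomes), but different genes in the 2 lines are not the whole cause, since within genes with clusters in both lines r was -0.72 (permutation p 6e-05, adjusted 6e-05; -0.58 without the same 2 chromosomes). The larger number of H9 clusters is not the whole cause either, since r was -0.77 (permutation p 2e-05, adjusted 2.67e-05; -0.64 without them) with as many H9 as LIN28-V5 293 clusters. Base composition, gene length, gene expression and the chromosome copies of each line were not tested and stay open, as do the antibodies and a biological difference between the lines.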
